A study of Drosophila melanogaster with 18 samples.

How the data were processed

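The study sequenced polyadenylated RNA of whole Drosophila melanogaster embryos from 6 mutant lines of a forward genetic screen for genes of muscle morphogenesis, in 18 samples. Per the labels' protocols, eggs were laid for 3 h at 25 °C, aged for 7 h to stage 12, and homozygous embryos were picked by hand with the help of a green fluorescent balancer chromosome. Variant lists of 3 lines were analysed here: sj266 (2 samples), sj440 (3 samples) and sj461 (3 samples). The labels number 2 replicates for each of these lines, which the design text calls technical, and the third sample of sj440 and of sj461 is a second sequencing run. The other 3 lines of the series were not analysed here.

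Per the submitters' processing notes, cutadapt 2.4, STAR 2.5.4b and the BDGP6 build were used, with no role or order given. The variant caller, its filters and the annotation program are not given in the sources used here. The authors deposited 1 list per line, with a position, reference and alternative bases, a quality score of the caller for each variant, and an annotated consequence, gene and transcript. The line of each list was taken from its worksheet's name within the workbook that the samples' description names. The lists of sj266 and sj440 came from the same workbook. The lists hold no read depth, no allele share and no values per replicate, so the depth behind a call is unknown and no test across replicates could be made. All listed variants had passed the authors' filter, lay on arms 2L or 2R and had a high or moderate impact. Shares on chromosome 2 and shares of protein-changing variants are therefore set by how the lists were composed, and the rule is not given in the sources used here.

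Entries that repeated a position and its alleles were merged, so that a distinct variant is 1 position with 1 pair of alleles. Coordinates are counted from 1 on BDGP6, and residues are numbered from 1 at the start of the protein of the annotated transcript. Gene symbols were matched to the RefSeq gene table of the Release 6 plus ISO1 MT assembly. All 129 genes matched, 8 of them under a newer symbol, and all 173 variants lay inside the gene's interval in that table. The annotation was checked for internal agreement only, without a genome. The codons of all 98 single-base coding changes translated to the listed residues. The reference base of all 47 splice-site variants was G or T at a donor, or A or G at an acceptor. As these values come from the same annotation, the checks do not test the calls.

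Shares have exact (Clopper-Pearson) 95% intervals, which cover counting error only. Lines were compared with two-sided Fisher's exact tests, Benjamini-Hochberg adjusted over the 3 pairs of lines. Quality scores of classes of variants were compared with two-sided permutation tests of the median (100000 draws), adjusted over 6 comparisons. The overlap with 14 gene lists was tested with a one-sided permutation test of 100000 draws, with genes drawn arm by arm from the 5508 protein-coding genes of chromosome 2. Chance was set in proportion to gene length because coding length was not used here, which departs from the plan. The plan's contrast of quality between protein-changing and other variants was replaced by one between insertions or deletions, splice-site variants and missense variants, since every listed variant is annotated as protein-changing. The threshold was an adjusted p of 0.05.

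Tests were run on simulated data first. The gene list test recovered 29 of 30 lists with 8 planted genes and called 0 of 30 sets without, over 5508 genes. The lists tested here held 3 to 40 genes of chromosome 2, and at most 2 genes of a list were hit. The simulation therefore does not show whether so few hits could be detected. The quality test recovered 49 of 50 sets with a 3-fold shift and called 4 of 50 sets without, at an unadjusted threshold.

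The genes named per line were set before the data were examined: up to 15 variants that disrupt a stop, a start or a splice site, by falling quality; members of the gene lists; the 8 other variants of highest quality; genes with variants in over 1 line, at most 10; and genes with 3 or more variants in a line, at most 5. The rule took 28 variants in 26 genes of sj266, 39 in 29 genes of sj440 and 36 in 28 genes of sj461. Alternatives fixed then were a quality minimum, the removal of clustered, shared or A-to-G variants, single-base changes alone, other matches between lines and other null models for the gene lists. Alternatives chosen after seeing the data were a quality of 150 or more, the removal of splice-site variants, the merging of equivalent insertions or deletions (same gene, line and net length within 30 bp), the high-impact share, the share on arm 2R, the replacement quality contrast and the gene-length null. The analysis used Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1, Biopython 1.88 and matplotlib 3.10.9.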

Results

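Variants called from embryo RNA were compared in 3 lines of a screen for genes of muscle morphogenesis. The question was which lesions each line carries in expressed genes, and whether the lines hold the same ones. The lists held 38 distinct variants in 35 genes for sj266, 68 in 55 genes for sj440 and 67 in 53 genes for sj461, in all 173 variants in 129 genes. Some insertions were listed more than once in equivalent form, and with these counted once the lists held 37, 66 and 64 variants. Each line has 1 list over its samples, so no count or share below has a replicate error, and read depth is unknown. Splice donor and acceptor bases lie in introns, which spliced RNA lacks. The reads behind the splice-site calls are unknown, and no effect on splicing was tested.

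In sj266 the variants of highest quality were 4 missense changes. They were V1973I in bark, a protein of junctions where 3 epithelial cells meet (2L, position 3798149, quality 220), E881K in the transporter gene Oatp30B (2L, 9537639, quality 215), E225K in the transcription elongation factor Spt5 (2R, 19438822, quality 213) and D770N in Tango1, which acts in collagen export from the endoplasmic reticulum (2L, 6652058, quality 207). The other variants of this line had a quality of at most 155. Splice-site variants made up 15 of its 38 variants, and the best of them had a quality of 104, at an acceptor of Asx, a Polycomb group gene (2R, 14507255). Others lay in IntS3, a subunit of the Integrator complex (quality 87), HmgZ (82), CG10737 (73), Lpin, a phosphatidate phosphatase (65), CG8814 and tei, listed as CG17716 (both 56). Splice-site variants of lower quality were listed in shn, a zinc finger regulator of the Dpp pathway (donor, 2R, 11214200, quality 53), galla-1 (45.3), CG9380 (43.4), the nucleoporin gene Gp210 (37.1), the type IV collagen gene Col4a1 (34.7), Nipped-A and Topors (both 27.4) and Spt5 (26.4). In-frame insertions lay in CG10543 (quality 155), CG44085 (111), B4 (106), CG4341 (89) and tou (54), and Eaf had an in-frame deletion (99). The line also had N264S in pyr, which encodes an FGF ligand of the mesodermal receptor Heartless (2R, 11724790, quality 63), and M79I and D991N in CG31897 (both 55).

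In sj440 the highest score of that list, 228, was reached by 5 variants in 5 genes. One was the stop gained C103* in NimC4, a receptor for the uptake of dying cells (2L, 14047939, in a gene that spans 14047582 to 14048863). The others were the missense changes A2539T in the large cadherin ds (2L, 644015), P167S in the zinc finger gene bowl (2L, 3780224), K755N in Lpin (2R, 8139721) and K793M in CG30015 (2R, 10841914). Next came R35Q in Gdi, which retrieves Rab proteins from membranes (2L, 9494512, quality 225), A639V in the transcription factor gene Sox14 (181), D842E in sha (179) and an in-frame insertion in the protease gene Np (173). Of 20 splice-site variants the one of highest quality lay at an acceptor of Aldh-III (139), followed by ClpP, listed as CG5045 (109), and a donor of Lpin (104). Adjacent bases of 1 donor of Pvr, the receptor of PDGF- and VEGF-related factors, were both changed (2L, 8222890 and 8222891, quality 100 each). Further splice-site variants were named in jhamt (78), CG7239 (73), CG15111 (57), the kinesin gene cmet (56), the adducin gene hts (54), fus (53), CG4972 and Dscam1 (both 52), sut1 (50) and HmgZ (30.4). Of muscle genes, Msp300, which anchors nuclei in muscle, had E94D and H95N (both 55) and T3021S (30.4), and the sarcomere gene Obsc, listed as Unc-89, had S568P and A531V (both 30.4). The line had N264S in pyr as well (quality 72), insertions in CG4341 (157 and 117) and CG44085 (131 and 127), M779I and G780S in CG31897 (both 26.4), and Q303P, S305P and K321I in CG30485 (all 39.4). Both entries of CG4341 write the same insertion at nearby positions, and so do both of CG44085.

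In sj461 the variant of highest quality was C313S in ptc, the Hedgehog receptor (2R, 8661096, quality 228, in a gene that spans 8649649 to 8665223). It was followed by V80M in CG7102 (2L, 7886585, quality 164), Y773N in the translation elongation factor eEF2 (2L, 21678529, quality 161), A15T in the matrix metalloproteinase Mmp2 (2R, 9682890, quality 156) and S513C in CG30460 (2R, 17068715, quality 153). The cadherin gene ds had another variant than in sj440, G118R (2L, 707415, quality 140). The start codon of ninaC, a myosin of photoreceptors, was changed by M1R (2L, 7378402, quality 78). Splice-site variants were found at an acceptor of the zinc finger gene Clamp (106), a donor of the synaptic scaffold gene Liprin-alpha (100), and in CG17646 (77), tou (68), Gint3 (63), l(2)gd1 (55), Klp31E (40.4), CalpA (30.4), CG9663 (27.4) and CG42260 (26.4). Among them were shot, which links actin and microtubules in tendon cells (donor, 2R, 13874857, quality 57), and robo2, a receptor of the guidance factor Slit (acceptor, 2L, 1394759, quality 36.7). Msp300 had K8249I (27.4). In-frame insertions lay in CG30122 (135), bib (129), Nak (121) and Np (equivalent entries of 107, 102 and 77), and cana had an in-frame deletion (127). Small genes with 3 or more changes were CG14947 (N131K, H8Q and S30C), CG15071 (L40P, G107A and L119I) and CG43402 (D70N, Y90F and the stop gained Y90*). Both changes in codon 90 of CG43402 had a quality of 30.4, and read together they give TTG, a leucine codon, so the listed stop depends on whether they lie on the same molecule. In sj440 the changes N57T and N57D of CG13324 share codon 57 in the same way and together give GCT, an alanine codon; this gene was named after its values were seen.

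**Figure D1:**
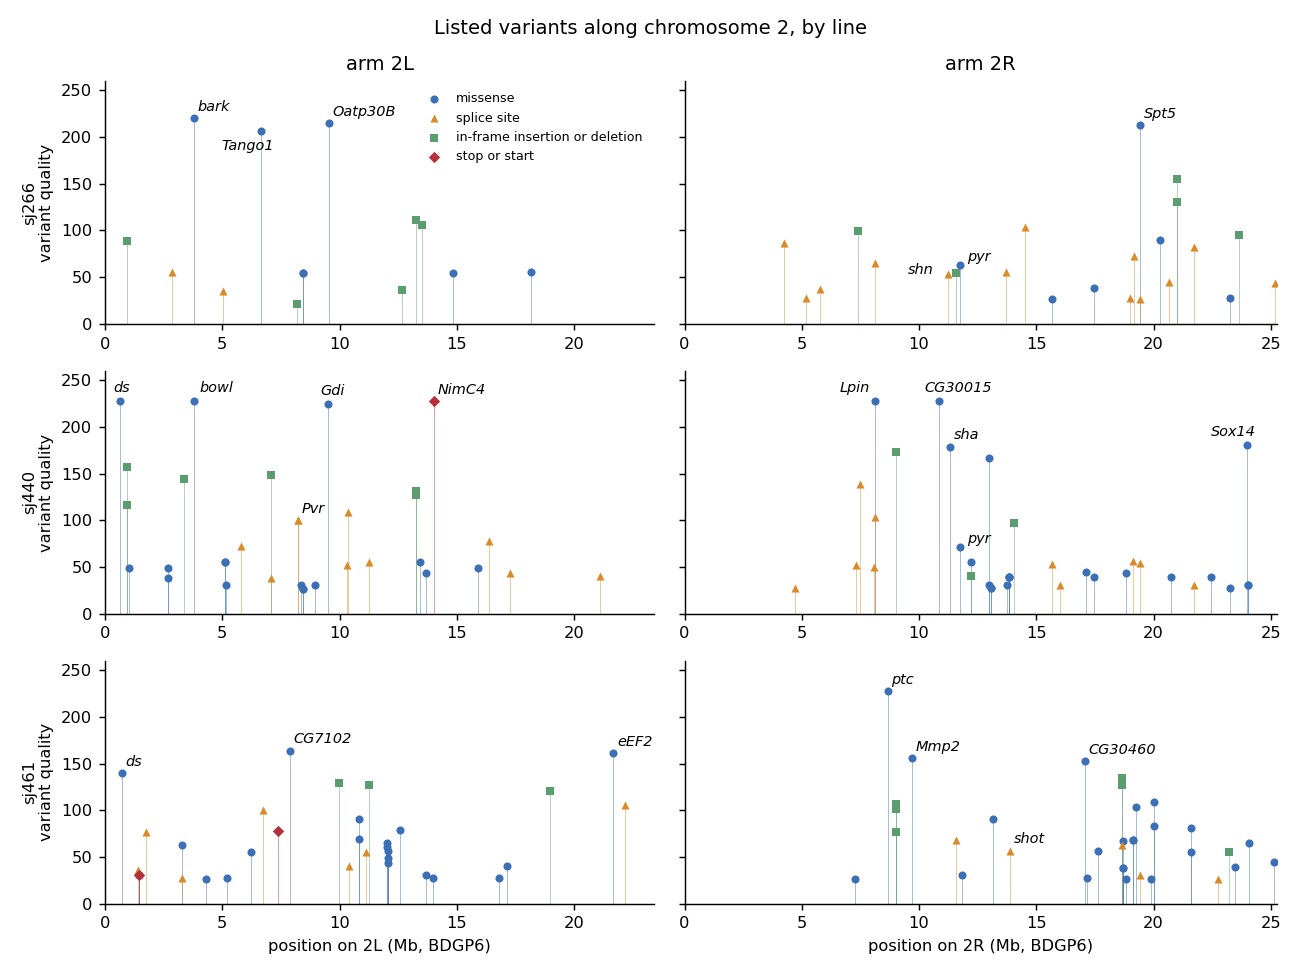
Each symbol is 1 listed variant at its position in Mb on arm 2L or 2R (BDGP6), with the caller's quality score on the vertical axis, for sj266, sj440 and sj461 from top to bottom; colour and shape give the class of change, and selected genes are named. The splice-site variants of all 3 lines lie at or below a quality of 139, while 5, 11 and 5 variants of the lines reach 150.

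Changes of G:C to A:T pairs, the type that alkylating mutagens mainly give, were the most frequent of 6 types in sj266 and sj440. The next type was A:T to G:C in sj266 (7 of 28, against 11) and A:T to T:A in sj440 (12 of 59, against 18). The G:C to A:T changes included the top 4 missense changes of sj266, in bark, Oatp30B, Spt5 and Tango1, and the changes in ds, bowl, Gdi and Sox14 of sj440. In sj461 they included CG7102, Mmp2 and ds, while ptc and eEF2 had changes of T:A to A:T pairs. The share was 39.3% of 28 single-base changes in sj266 (exact 95% interval 21.5 to 59.4), 30.5% of 59 in sj440 (19.2 to 43.9) and 24.1% of 58 in sj461 (13.9 to 37.2). In sj461, 14 changes of A:T to T:A equalled the 14 of G:C to A:T. The lines were not told apart by this share: two-sided Fisher's exact tests gave an adjusted p of 0.535 for each of the 3 pairs. Among changes with a quality of 150 or more, a limit chosen after seeing the data, the share was 100% of 4, 44.4% of 9 and 40% of 5. The exact 95% intervals were wide (39.8 to 100, 13.7 to 78.8 and 5.27 to 85.3). At this quality A:T to T:A changes were 0 of 4, 4 of 9 and 3 of 5, equal to G:C to A:T in sj440 and above it in sj461. The mutagen is not named in the labels, and the most frequent type does not identify one.

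**Figure D2:**
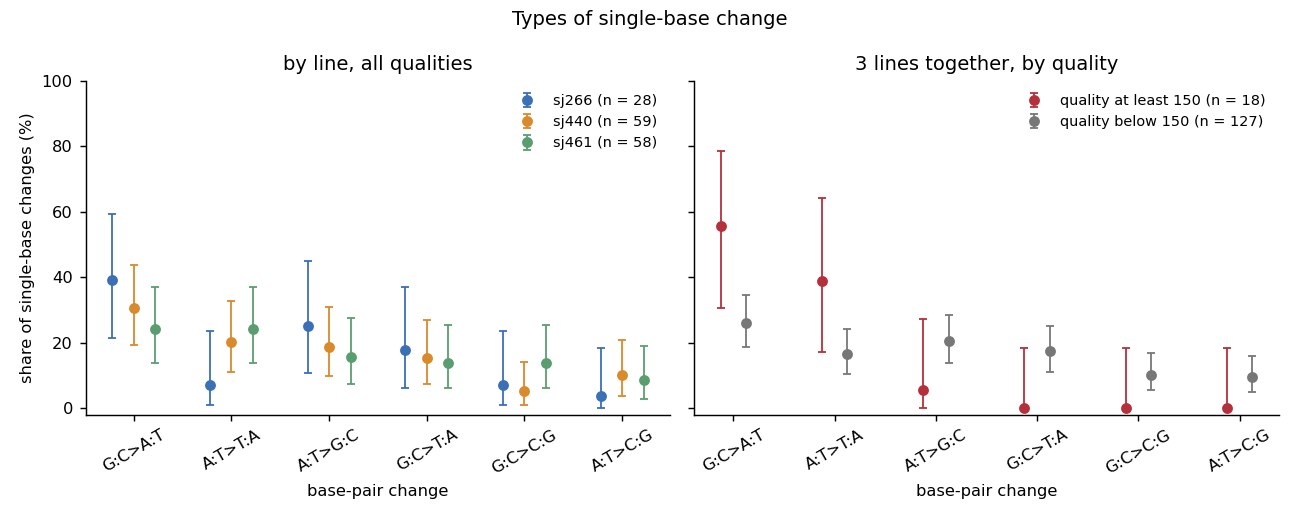
The vertical axis gives the percentage of single-base changes of each base-pair type, shown on the horizontal axis, with exact 95% intervals as bars, on the left for each line and on the right for the 3 lines together by quality. G:C to A:T lies at 39.3%, 30.5% and 24.1% in sj266, sj440 and sj461, with overlapping intervals, and at quality 150 or more 17 of 18 changes are G:C to A:T or A:T to T:A.

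Missense changes were 13 of 38 variants in sj266, 38 of 68 in sj440 and 44 of 67 in sj461. Splice donor or acceptor changes were 15, 20 and 12, in-frame insertions or deletions 10, 9 and 9, and changes of a stop or start codon 0, 1 and 2, these last in NimC4, ninaC and CG43402. No frameshift was listed among 28 insertions and deletions. The high-impact share (splice sites, stops gained and starts lost) was 39.5% in sj266 (exact 95% interval 24 to 56.6), 30.9% in sj440 (20.2 to 43.3) and 20.9% in sj461 (11.9 to 32.6). Splice-site variants were 15 of the 15 high-impact variants in sj266, 20 of 21 in sj440 and 12 of 14 in sj461. The share is therefore mainly one of splice-site calls. No pair of lines passed Fisher's exact test, with adjusted p of 0.398 for sj266 against sj440, 0.204 for sj266 against sj461 and 0.359 for sj440 against sj461. Every listed variant was annotated as protein-changing (100% in each line, splice-site variants included), so that share carries no comparison. No effect on a protein was measured.

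All variants of the 3 lists lay on chromosome 2, with 14 on 2L and 24 on 2R in sj266, 33 and 35 in sj440, and 33 and 34 in sj461. In sj461 both arms held variants of high quality, ptc, Mmp2 and CG30460 on 2R and CG7102 and eEF2 on 2L. In sj266 bark, Oatp30B and Tango1 lay on 2L and Spt5 on 2R. The chromosome holds 35.2% of the length of protein-coding genes in the gene table, but as the lists hold no other chromosome, the exact binomial p-values (5.56e-18 in sj266, 1.33e-31 in sj440, 3.78e-31 in sj461) describe the composition of the lists. The share on 2R was 63.2% (exact 95% interval 46 to 78.2), 51.5% (39 to 63.8) and 50.7% (38.2 to 63.2), against 51.8% of chromosome 2 gene length. Two-sided exact binomial tests gave p = 0.194, 1 and 0.903.

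Identical variants were found in sj266 and sj440, 6 in all. They were N264S in pyr, a splice donor change in Lpin (2R, 8141889), a splice donor change in HmgZ (2R, 21704322), S151G in CG10764 (2R, 17454274), D444E in ord, a gene of meiotic cohesion (2R, 23272142), and an insertion of 3 bases in CG4341 (2L, 952951). Their quality in sj266 and sj440 was 63 and 72 for pyr, 65 and 104 for Lpin, 82 and 30.4 for HmgZ, 38.4 and 39.4 for CG10764, 27.4 and 27.4 for ord, and 89 and 157 for CG4341. No identical variant joined sj461 to either line. Genes with variants in more than 1 line numbered 14, of which 8 joined sj266 and sj440, 5 joined sj440 and sj461 (ds, Msp300, Np, CG15082 and DIP-kappa) and 1 joined sj266 and sj461 (tou). Of these, CG10764, ord, CG15082 and DIP-kappa fall outside the rule's limit of 10 such genes and were named after their values were seen. No gene was listed in all 3 lines. G:C to A:T changes were 0 of 5 shared single-base changes and 43 of 135 line-specific ones, with a two-sided p of 0.323 in Fisher's exact test. With 5 shared changes even this lowest possible count could not pass the threshold, so the test cannot show a deficit.

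Each muscle and signalling list held at most 2 of the genes hit. Muscle identity held pyr, muscle guidance and attachment held robo2, tendon cell development held shot, and myonuclear position held Msp300. Receptor tyrosine kinase signalling held pyr and Pvr, Hedgehog signalling held ptc, Wnt and Dpp signalling held shn, and the sarcomere list held Obsc. The list of trachea, gut, haemocyte and fat body genes held Pvr, and that of ribosomal proteins and translation factors held eEF2. Myoblast fusion, segmentation, mitosis and the nervous system held none, with 0 of 12, 0 of 14, 0 of 18 and 0 of 8 list genes of chromosome 2. Over the 129 genes, 0 of 14 lists were hit more often than in gene sets drawn by arm and gene length (one-sided permutation test, adjusted p of 1 for each list, and 0 lists at an unadjusted p under 0.05). The draws were not limited to genes expressed in the embryo, the only ones that calls from RNA can show. Gene length took the place of the planned coding length. The expected hits depend on this choice in both directions. Muscle guidance had 2.56 expected by gene length and 0.514 with an equal chance per gene, and the translation list had 0.246 and 0.932. With an equal chance per gene, the receptor tyrosine kinase list had an unadjusted permutation p of 0.0296 (adjusted 0.415). At a quality of 150 or more the translation list had an unadjusted permutation p of 0.0382 (adjusted 0.399). The smallest unadjusted p over the 3 lines together was 0.0976, for Pvr in the trachea, gut and haemocyte list, where 0.0997 genes were expected. Line by line the smallest was 0.041, for the same gene in sj440 (adjusted permutation p = 0.574). The Pvr hit rests on adjacent bases of 1 splice donor. Without variants within 100 bp of another, or without splice-site variants, the trachea list held 0 genes and the receptor tyrosine kinase list 1.

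The insertions in CG10543, Np, CG4341 and bib had quality scores above the median of their line, and the highest missense scores, in bark, ds, bowl and ptc, lay above them. The median quality of insertions and deletions was 97 in sj266, 131 in sj440 and 121 in sj461, against 56, 41.4 and 57 for missense changes. As the caller is not given, it is unknown whether it scores both kinds on the same scale. A higher median therefore need not mean better-supported calls. Only sj461 passed the permutation test (adjusted p = 0.0484, 9 against 44 variants), while sj266 (0.36) and sj440 (0.107) did not. The median quality of splice-site variants was 53, 53.5 and 56, and none of the 3 lines passed the same permutation test against missense changes (adjusted p = 0.456, 0.184 and 0.991). Without A-to-G changes, sj266 passed it, with medians of 54.5 for 14 splice-site variants and 90 for 9 missense changes (adjusted permutation p = 0.0437), and without shared variants its medians were 45.3 and 73 (adjusted permutation p = 0.107). Over all classes the median quality was 56 in sj266 (range 21.2 to 220), 52 in sj440 (26.4 to 228) and 63 in sj461 (26.4 to 228). The 9 insertions and deletions of sj461 include 3 equivalent entries of Np and 2 of CG30122, and with each counted once the call was lost (adjusted permutation p = 0.0668, 6 against 44 variants, medians 124 and 57). It was lost as well without variants within 100 bp of another (adjusted permutation p = 0.37), where the medians, 124 and 57, were as far apart but only 4 and 30 variants were left.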

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

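All tests in this part were chosen or fixed after the result they bear on had been seen in whole or in part.

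The number of identical variants differed between pairs of lines: 6 joined sj266 and sj440 (in pyr, Lpin, HmgZ, CG10764, ord and CG4341), and 0 joined either line to sj461. With pairs weighted by list size, all 6 falling in this pair had a two-sided exact binomial p of 0.00036. That test treats the 6 variants as independent. All except the CG4341 insertion lay on 2R, and variants inherited together are not independent. If they have a common origin, this pair would be drawn in 26.7% of cases by list size. The test therefore cannot exclude the sizes of the lists. Adenosine-to-inosine editing of the RNA is excluded as the whole source, since 3 of the 5 shared single-base changes were of another type than A to G. Processing of the lists in one workbook stays open: sj266 and sj440 came from the same workbook, and 0 further pairs of this kind were analysed here (the workbook of sj461 is also named for sj287, whose list was not analysed here), so it cannot be told apart from a common parental stock. A common stock is a candidate explanation that the design does not test.

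On the strand that has the sequence of the RNA (not the template strand), G to A changes outnumbered C to T changes 35 to 8. The balance among coding changes differed between lines (permutation p = 0.0052): 6 to 0 in sj266, 5 to 7 in sj440 and 11 to 1 in sj461. Splice sites hold G and no C, which accounts for their 13 to 0, but the coding changes alone had a G to A share of 73.3%, with a 95% lower bound of 54.1% against 52.4% of protein-changing codon changes with equal codon use. Whether a single line carries the coding share is open: the lower bound was 35.7% without sj461 and 44.7% without sj266, both under 52.4%, and 72.7% without sj440, but leaving out a line also leaves fewer changes, and sj266 and sj461 each lay above 52.4% alone (lower bounds 54.1% and 61.5%). Pairwise Fisher's exact tests missed the threshold (adjusted p = 0.0566 for sj440 against either line), and codon use of the genes was not tested. The lines are the only biological difference in the design, and no biological explanation was tested.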

How the results depend on the processing

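No pairwise comparison of lines in the G:C to A:T share, the high-impact share or the 2R share changed its side of the threshold under the settings run, and the gene list overlap stayed at 0 lists in each. Some differences reversed their sign. The high-impact share of sj266 minus sj440 was 8.59 percentage points, and -6.67 at or above the median quality. The 2R share of sj266 minus sj440 was 11.7 points, and -4.26 without splice-site variants. The chromosome 2 and protein-changing shares were left aside, since the composition of the lists fixes them at 100% in any setting. Among the other main results, 47 planned and 79 added settings were counted as kept, and 5 and 15 as moved. Kept does not mean equal. Without variants within 100 bp of another, sj461 had 47 variants in place of 67. Without splice-site variants, the 2R share of sj266 was 47.8% in place of 63.2%. These counts are therefore no measure of stability. Of the 103 variants named by rule, 66 had a quality at or above their list's median, 61 were left without splice-site variants and 20 had a quality of 150 or more. A quality at or above each list's median left 21 variants in sj266, 35 in sj440 and 34 in sj461, and a quality of 150 or more left 5, 11 and 5, by construction. Leaving out splice-site variants left 23 in sj266. At a quality of 150 or more, the G:C to A:T share was 100%, 44.4% and 40%, the high-impact share 0%, 9.09% and 0%, and the 2R share of sj266 was 40%. Matching by gene gave 14 shared items in place of 6. The number of quality comparisons past the threshold, 1, was 0 for single-base changes only, since the one called concerns insertions and deletions, 0 without variants within 100 bp of another, 0 with equivalent insertions or deletions counted once, at their first position or at their highest quality, and 2 without A-to-G changes, which add splice-site against missense variants of sj266. Fewer variants entered these settings, and the cause was not tested further. The share of genes on chromosome 2, 39.4%, in place of gene length leaves the lists at 100%. No paired analysis was possible because each list pools the replicates of its line, so leaving out a replicate was not run either. A depth minimum, annotation over several transcripts, an annotation from a genome and a null from coding length were not run, as depth, other transcripts, a genome and coding lengths were not used here. Without depth, the reliability of a call rests on the caller's quality score alone.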

Other observations

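The insertions and deletions were short in-frame changes, many of them in runs of 1 residue. All 28 changed the length by a multiple of 3 bases. With equivalent entries of a gene merged within and between lines, 21 remained, of which 6 added or removed glutamines only and 3 serines only. Examples, chosen after their values were seen, were mam, the coactivator of Notch (sj440, quality 97), and bib, a neurogenic gene (sj461, quality 129), which both gained glutamines, and pdm2, a POU-domain gene (sj266, quality 36.3), which lost an alanine.

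The tests in this paragraph were chosen after the pattern was seen. Of 18 single-base changes with a quality of 150 or more, 17 were G:C to A:T (10) or A:T to T:A (7), against 54 of 127 below it; they include ptc, eEF2, ds, bark, Spt5 and NimC4, and the exception, also named after its values were seen, is S180P in Su(z)2 (sj440). Choice of the quality threshold and of the types does not account for it: the largest excess over 51 thresholds and 15 pairs of types was reached with a frequency of 0.0036 among 10000 shuffles within lines. Splice-site calls at low quality are excluded as the whole cause, since the excess was 51.9 percentage points with them and 54.4 without (permutation p = 0.0001 from shuffles, the smallest possible), and so is clustered polymorphism, with 53.3 points without clustered variants (permutation p = 0.0002). Read depth, which can set the quality, was not tested. A candidate explanation, as a hypothesis, is that the high-quality set is richer in induced lesions than the rest, which may hold inherited variants and errors; the labels name no mutagen, and no unmutagenised parent was analysed here.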
